A study of Saccharomyces cerevisiae with 232 samples.

How the data were processed

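The series held 232 samples: 127 footprint libraries treated with cycloheximide (14 wild-type libraries, 57 deletion strains), 67 RNA libraries (10 wild-type), 6 footprint libraries without the drug and 32 RiboMeth-seq libraries. Per the labels, the strains grew in rich medium at 30 °C, the drug was given at 100 µg/mL for 30 s, and footprints came from monosomes after digestion with RNase I. The RiboMeth-seq libraries were 2 of each of BY4741, trm3D, trm7D, trm13D, trm44D, trm732D and rtt10D, and 6 further libraries of each of BY4741, trm7D and trm3D, whose labels combine 2 numbers with 3 end treatments. The labels do not state whether libraries of one strain came from separate cultures, so p-values measure the spread between samples only.

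The expression values were deposited by the authors as RPKM (reads per kilobase and M mapped reads) for 6692 genes. Per the submitters' processing notes, adapters were removed, reads of 27 nt (RNA) or 27 to 34 nt (footprints) were kept, reads from rDNA were discarded, and uniquely mapped reads were placed on sacCer3 with TopHat2 2.0.12, SAMtools and HOMER 4.6. The authors also deposited a ratio table of 4884 genes, the footprint value plus 1 over the RNA value plus 1 in a strain over wild type, whose filter is not stated. The codon table was deposited as log2 fold changes of codon frequency at the A, P and E sites relative to wild type, and its reference and codon assignment rule are not stated. In its A-site and P-site columns trm12D stands under the synonym tyw2D, and 2 columns that repeat it at the E site were not used here. Wild-type library 10 has no column there, which leaves 13 wild-type libraries. The RiboMeth-seq table was deposited as counts of 5′ ends at 5475 positions of the 4 rRNAs, so the tRNA positions set down beforehand were not analysed here and rRNA positions were scored in their place, a choice made after seeing the data.

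Each library's depth was recovered from the RPKM values and the coding lengths of the reference annotation, whose build, R64, is that of sacCer3; 6008 gene identifiers matched it and 6007 had a coding length. Within 0.1 reads, 90.6% to 98.0% of values of up to 20 reads were whole, where chance gives 20%. Depths were 0.810 to 16.25 M reads for footprints, 3.76 to 14.1 M for RNA, 3.42 to 7.35 M (median 6.24 M) for drug-free footprints, and 14.1 to 26.6 M 5′ ends (median 19.6 M) for RiboMeth-seq. PCR copies were not distinguished by molecular identifiers.

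The divisors of the ratio table placed 56 strains in 3 processing sets, with a largest median deviation under 0.0004 log2, and 2 columns of dus2D matched no set. The sets tie columns to wild-type libraries by the numbers in their names. In a principal component analysis of the footprints, components 1 and 2 held 21.4% and 15.3% of the variance, and the wild-type means on component 2 were −12.4, 3.13 and −1.51 in sets 1, 2 and 3. Wild-type libraries of one set had a median Pearson r of 0.996 and those of different sets 0.984. Among footprint libraries of wild type and of the same strain, no pair was a copy (smallest chi-square per gene 1.22 between wild-type libraries and 1.36 between libraries of a strain).

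Values were taken as log2 of RPKM plus 1, without further scaling. Genes with a mean of at least 10 RPKM were tested: 4281 for footprints, 5031 for RNA and 4253 for translational efficiency. Linear models with all wild-type libraries as reference were fitted with limma 3.58.1 (empirical Bayes with a trend), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Contrasts were each strain with 2 footprint libraries, and the mean over strains of a pathway, with 24 pathways set down beforehand. In the footprint fit each strain has its own coefficient. The SE and p of a pathway mean there measure the spread between libraries of the same strain, not between the strains of the pathway. List tests on footprints rest on the same fit. RNA was tested only for the Elongator and thiolation groups, since a strain has 1 RNA library. For single strains, genes outside the range of the wild-type RNA libraries and at least 2-fold from their mean were counted. Translational efficiency was tested as the interaction of assay and group. That model has no term for the strain, so the footprint libraries of one strain count there as separate samples. The correlation of both groups' changes was set against 100 simulated unchanged groups, and the overlap of their calls, with separate wild-type libraries, against independent lists. The choice of groups, tests, gene lists and alternatives was made before the data were examined, except where stated.

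Of 20 gene lists, 16 had at least 3 measured members in the footprints and were tested with camera (preset correlation 0.01), and again with an estimated correlation and with fry. The mitochondrially encoded genes were tested in RNA alone. Lists are given as members called over all genes and called when adjusted over the list alone. The direction of the median and of the test differed in sign for these lists: histones, in Elongator strains; aminoacyl-tRNA synthetases, a-specific and PAU and COS genes, in thiolation strains; the Aft1 regulon and histones, in trm9D and trm112D; PAU and COS genes, in the Sit4 and KEOPS groups; glycolytic genes, in pseudouridine strains. In Elongator RNA these were Msn2/4 genes and histones, in Elongator translational efficiency ribosome biogenesis, Pho4 and sulfur genes, and in thiolation translational efficiency aminoacyl-tRNA synthetases.

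Genes were named by a rule set down beforehand. It names each deleted gene in its own strain, GCN4, and in each pathway contrast up to 10 largest rises and 10 largest falls among called genes that changed the same way in every strain, without the deleted genes. It names the same for the 3 strains with most footprint calls, where both libraries had to go the same way, up to 4 members of each list with the smallest adjusted p, the target codons of each pathway, and the 10 strain-codon pairs with the largest change. The genes named for the difference between Elongator and thiolation strains, and those named from the drug-free libraries outside this rule, were chosen after their values were seen. Not every gene that the rule names is reported. Genes that overlap another gene, and close paralogs such as RPS9A, RPL8A, PHO11, PHO12 and TDH2, share reads or positions, so their values are uncertain. YHR180W-A, YMR173W-A and YPR039W are not in the reference annotation.

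Codon changes were tested per strain and codon with limma (without a trend), over 61 codons and 57 strains; the median SD of a codon over the 13 wild-type libraries was 0.031. Pathway means over their target codons were set against strains outside the pathway, and outside the wobble uridine pathways, by exact permutation of strains (41 tests adjusted together). Strains that stand alone in their pathway were ranked against the other 56 (12 tests adjusted together).

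RiboMeth-seq scores were 1 minus the count at the position following each nucleotide over the weighted mean of 6 neighbours on each side (weights falling by 0.1 per step), without a coverage minimum. Positions over 0.9 in wild type were called protected and under 0.5 lost. The last 50 nucleotides of each rRNA (200 positions) were left out, a choice made after seeing the data. Scores of wild-type libraries had a Pearson r of 0.994. Drug-free changes were compared with the drug-treated changes over 4122 genes.

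The tests were tried on simulated data with 200 changed genes. Of these 96.5% were recovered for 1 strain with 2 libraries (90.7% of 75 genes changed 1.5-fold), with 5.39% false among the calls. For the Elongator group 99.5% were recovered with 4.78% false, for KEOPS 99% with 7.48% false, for Elongator RNA 99.5% with 2.93% false, and for edgeR 96.5% with 3.5% false. Codon changes of 0.1, 0.3 and 0.6 log2 were recovered in 47.4%, 95% and 100%, with 3 false calls of 3477. With no change, camera gave 4.39% of lists an unadjusted p under 0.05. The simulated genes and codons were drawn independently, without correlation between genes and without a difference between processing sets. These rates therefore need not hold for the real libraries, and they do not show that the list tests are calibrated there.

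Alternatives set down beforehand were pseudocounts of 0.1 and 5, no filter, a mean of at least 50 RPKM, median centring, quantile normalization, rescaling without ribosomal protein genes, the mean of all deletion strains as reference, a replicate block, leaving out replicate 1 or 2 and each strain in turn, 1 value per strain, an additional 1.5-fold threshold, and edgeR 4.0.16 (quasi-likelihood, 4245 genes) on recovered reads. For codons they were centring on the median codon and the deletion-strain mean as reference. For RiboMeth-seq they were a window of 4 neighbours and a coverage minimum of 10, and for drug-free libraries the filter and pseudocount were varied. Added after seeing the data were the processing set as a term, leaving out doubted libraries (under 1 M reads, or over 5% of wild type left at the deleted gene), codon tests within a set, the KEOPS codons against the wild type of their set, separate wild-type libraries for the overlap, and for RiboMeth-seq the rRNA positions, the 3′ ends kept and a score over 0.8. Values were computed with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3.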

Results

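The series asked how the loss of tRNA modifications changes translation in budding yeast, Saccharomyces cerevisiae. Deletion strains of the BY4741 background, a standard haploid laboratory strain of mating type a, each lacked 1 gene that modifies tRNA or helps to do so. A strain is named by its deleted gene followed by D, so that elp3D lacks ELP3. Ribosome-protected footprints (RPF), the pieces of mRNA shielded by translating ribosomes, were sequenced in 127 libraries treated with cycloheximide, a drug that arrests elongating ribosomes. These were 14 wild-type libraries and libraries of 57 strains, 2 for each of 56 strains and 1 for kti13D. Total RNA was sequenced in 67 libraries, 10 of wild type and 1 of each strain. A further 6 footprint libraries were made without the drug, and 32 libraries measured ribose methylation of rRNA by RiboMeth-seq, which counts where fragments of alkaline-cleaved RNA begin. Recovered reads per library ranged from 0.810 to 16.25 M (M, 1e6 reads; median 3.11 M) for footprints and from 3.76 to 14.1 M (median 10.4 M) for RNA.

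The deleted gene was checked first in every strain. Its footprints lay below those of every wild-type library in 57 of 57 strains, and its RNA lay below every wild-type RNA library in 57 of 57 strains. The footprints left at the deleted gene, in the higher of a strain's libraries, had a median of 1.41% of the wild-type mean. The largest value was 26.6%, in library 1 of ncs6D, and 7 strains kept more than 5% in at least 1 library.

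The libraries fell into 3 processing sets, read from which wild-type mean served as divisor in the authors' ratio table. Set 1 held 11 strains with 6 wild-type footprint libraries, set 2 held 39 strains with 4, and set 3 held 6 strains with 4, while dus2D matched no set. Wild-type libraries differed between sets in 2216 genes (set 1 against set 2), 1592 genes (set 1 against set 3) and 1193 genes (set 2 against set 3) of 4281 tested. Counts with the set as a term, in which each strain was compared with the wild type of its own set, are therefore printed beside most counts against all wild-type libraries.

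Strains lacking parts of KEOPS, the complex that makes the threonylcarbamoyl group of tRNAs reading codons that begin with A, had 3079 genes called in gon7D, 2852 in bud32D and 1454 in cgi121D of 4281 tested (2888, 2616 and 1210 with the set as a term). The strain trm112D, which lacks an activator shared by several methyltransferases, had 3033 calls, and with the set as a term it had the most of all strains (3082). The strain sit4D, which lacks a protein phosphatase, had 2167 (1944 with the set as a term), and trm7D, which lacks a ribose methyltransferase of the anticodon loop, had 2037 (1952). In isu2D, trm2D and trm3D the single call was the deleted gene. Over the 56 strains with 2 libraries there were 39194 gene-by-strain calls, 24399 higher and 14795 lower, and 42 strains had at least 20 (limma, adjusted p under 0.05). The split turned to 17105 higher and 20957 lower with median centring and to 17652 and 20107 with quantile normalization. There were 28618 calls with the set as a term, and 28 strains then had at least 20.

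**Figure D1:**
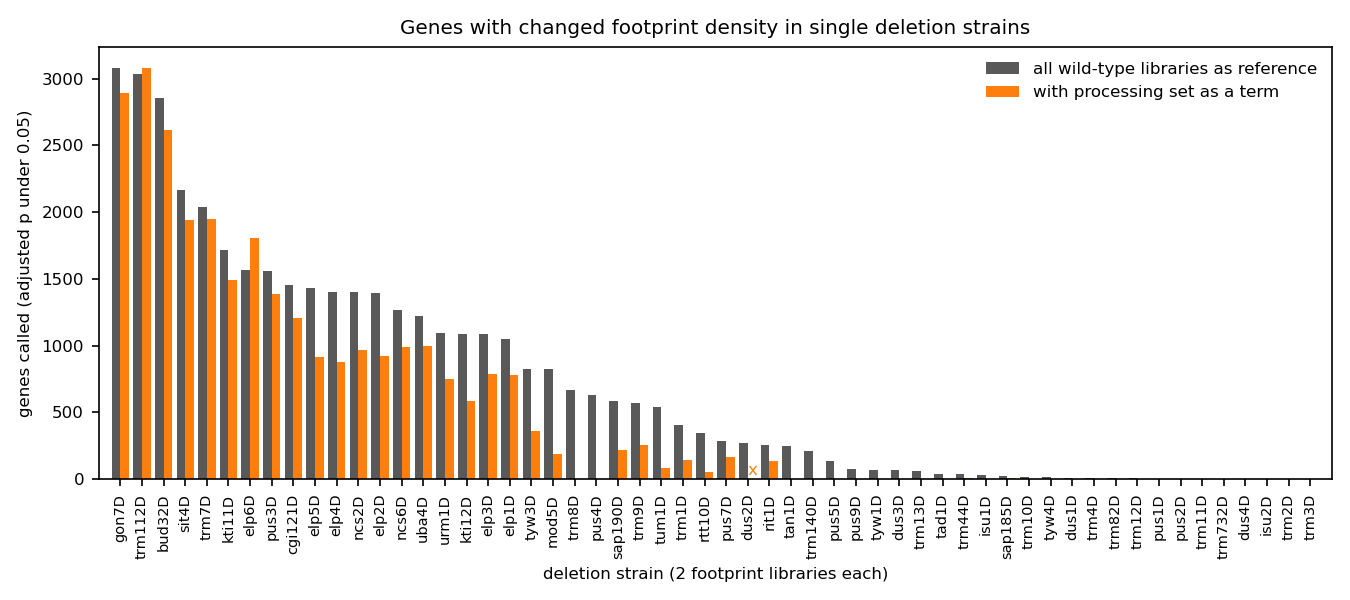
Genes called in the footprints of each deletion strain (y axis, number of genes with limma adjusted p under 0.05 of 4281 tested; x axis, strains with 2 libraries), against all wild-type libraries and with the processing set as a term; dus2D, which matched no set, is marked with x. The strains gon7D (3079), trm112D (3033) and bud32D (2852) lead without the term, and trm8D falls from 668 to 2 calls with the set as a term.

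Among the 3 strains with most calls, gon7D had HSP12, a stress-induced membrane protein gene, 6.66 higher on the log2 scale, and SNZ1 and SNO1, which make vitamin B6, 6.29 and 5.70 higher. Phosphate-regulated genes lay lowest in gon7D, with SPL2 at −5.81, PHO12 at −5.37 and PHM6 at −5.17. The phosphate transporter gene PHO84 stood at −4.70 and overlaps an RNA gene on the opposite strand. HO, the mating-type switching endonuclease gene, was also lower (−4.42, SE 0.083). In bud32D, HSP12 (4.90), the small heat-shock protein gene HSP26 (4.10) and SNZ1 (3.78) rose, while the cell wall mannoprotein gene TIR1 (−4.90) and PHO12 (−4.68) fell. In trm112D, ARO10 (3.37), the mating pheromone gene MFA1 (2.56) and ARO9 (2.49) rose, and PHO5 (−4.49), DDR48 (−4.14) and HIS4 (−3.14) fell. Each of these changes went the same way in both libraries of its strain, and library 2 of trm112D was the shallowest of all footprint libraries (0.810 M reads).

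Elongator, with its Kti partners, builds the side chain on the wobble uridine of several tRNAs. In 9 strains lacking it (17 libraries), the largest footprint rise was that of ARO10, the phenylpyruvate decarboxylase gene of aromatic amino acid breakdown, from 9.29 to 121 RPKM (log2 change 3.60, SE 0.176; 3.15 to 4.38 in the single strains). ARO9, the aromatic aminotransferase of the same pathway, rose by 3.01 (SE 0.125). GCN4, the transcription activator of amino acid synthesis, rose by 1.75 (SE 0.126), and the stress activator gene MSN4 by 1.56. The deepest falls were those of YGP1, a secreted starvation glycoprotein gene (−2.56, SE 0.167), TIR1 (−2.46, SE 0.099) and PHO5, a secreted acid phosphatase gene (−2.38, SE 0.156). PHO11 (−1.75), the siderophore transporter gene ARN2 (−1.61), the cell surface gene MRH1 (−1.61), ANB1 (−1.58), which encodes the anaerobic form of an elongation factor, and TYE7 (−1.53), an activator of glycolytic genes, also fell. YGL088W fell as well (−1.52) but overlaps the small nucleolar RNA gene SNR10, so its value is uncertain.

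Of 41 measured Gcn4 targets in amino acid synthesis, 34 rose and 2 fell in these strains, with 37 called when adjusted over the list alone. LEU4 of leucine synthesis (1.05), LYS2 of lysine synthesis (1.14) and ARG4 of arginine synthesis (1.77) were among the members with the smallest adjusted p. The list stood above the other genes (camera, adjusted p = 3.88e-19; adjusted p = 0.00812 with an estimated correlation). Of 32 proteasome genes, 24 rose and 4 fell (28 adjusted over the list alone), led by RPN6 (0.69) and PRE3 (0.73), with adjusted p = 1.65e-10, and adjusted p = 0.0378 with an estimated correlation. Of 35 oxidative phosphorylation genes, 28 rose and 1 fell (31 adjusted over the list alone), among them COR1 (0.73) and SDH2 (0.67), but the list's adjusted p of 2.19e-04 became an adjusted p = 0.490 with an estimated correlation. Of 16 glycolytic genes, 1 rose and 11 fell (12 adjusted over the list alone), including HXK2 (−0.67) and TDH2 (−0.66), with adjusted p = 4.71e-07, and adjusted p = 0.346 with an estimated correlation. Of 16 Pho4 targets, the phosphate starvation genes, 0 rose and 12 fell by limma (12 adjusted over the list alone), with adjusted p = 5.89e-08, and adjusted p = 0.230 with an estimated correlation. Of 137 ribosomal protein genes, 9 rose and 46 fell (52 adjusted over the list alone; adjusted p = 2.26e-06, and adjusted p = 0.613 with an estimated correlation). Sulfur amino acid genes (3 rose and 10 fell of 17, MET2 at −1.16), the Aft1 iron regulon (4 and 9 of 22) and a-specific genes (0 and 3 of 7) also stood lower, and ribosome biogenesis genes (35 and 4 of 62) higher, at adjusted p of 0.00569, 0.0190, 0.0365 and 0.0359. With an estimated correlation these adjusted p were 0.507, 0.795, 0.645 and 0.839. Lists of Hsf1 chaperones (13 rose and 1 fell of 24), Msn2/4 stress genes (7 and 2 of 16), aminoacyl-tRNA synthetases (9 and 5 of 19), histones (2 and 1 of 10), pheromone response (1 and 5 of 10) and subtelomeric PAU and COS genes (2 and 0 of 3) did not stand apart, at adjusted p of 0.0666, 0.911, 0.782, 0.609, 0.160 and 0.805. In all, 1559 genes rose and 776 fell in the Elongator strains, of 4281 tested. With the set as a term 2449 genes were called, and 2185 of the 2335 were called again in the same direction. The split was 1063 higher and 1242 lower with median centring, and 1133 and 1168 with quantile normalization.

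The RNA of the same genes was tested over the 9 Elongator strains with 1 RNA library each. ARO10 RNA rose by 2.99 (SE 0.089), ARO9 by 2.02 and ARG4 by 1.59, and TIR1 (−2.25), PHO5 (−2.01) and TYE7 (−1.73) fell. Of 39 Gcn4 targets measured, 37 rose and 0 fell by limma (37 adjusted over the list alone), with adjusted p = 5.83e-15, and adjusted p = 0.386 with an estimated correlation. Proteasome genes rose in RNA too (20 up and 3 down of 32; adjusted p = 1.85e-07, and adjusted p = 0.386 with an estimated correlation). The mitochondrially encoded genes, which footprints did not measure, rose as well: 8 of 8, with COX2 at 0.90 and COX3 at 0.80 (adjusted p = 4.94e-05, and adjusted p = 0.446 with an estimated correlation). In all, 1424 genes rose and 949 fell in RNA of 5031 tested (2612 calls with the set as a term).

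Few genes were called in translational efficiency, the footprint change beyond the RNA change. The share of changes that this test recovers was not simulated. GCN4 had the largest rise in the Elongator strains (1.55, SE 0.245, adjusted p = 3.55e-05 by the limma interaction model). YBR056W-A, a small gene of unknown function, rose by 1.44, SER3, which makes serine, by 1.01 and ARO9 by 0.99, although SER3 overlaps the upstream transcript SRG1. CPA1, an arginine synthesis gene, fell by 0.84 (SE 0.094), ARN2 by 0.94 and RPL22B by 0.80. Gcn4 targets as a list did not stand apart in translational efficiency (3 rose and 1 fell of 39, adjusted p = 0.106). In all, 66 genes rose and 16 fell of 4253 tested (82 calls; 619 genes at an unadjusted p under 0.05). The set term gave 382 calls (308 higher and 74 lower), and leaving out elp5D gave 51. The split was 23 higher and 34 lower with median centring, and 48 and 38 with quantile normalization.

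The Urm1 pathway adds sulfur to the same wobble uridine. In 5 strains lacking it (10 libraries), ARO10 rose by 2.36 (SE 0.200), ARO9 by 2.06 and GCN4 by 1.32 (SE 0.143). SER3 (1.46), LYS1 of lysine synthesis (1.28) and IMD2 of guanine nucleotide synthesis (1.16) also rose, SER3 with the same overlap. TIR1 (−1.66), YGP1 (−1.65), PHO5 (−1.53), ANB1 (−1.25), the sodium-phosphate transporter gene PHO89 (−1.22) and MET2 of methionine synthesis (−1.19) fell. YGL088W had −1.20 against all wild-type libraries and −0.50 with the set as a term (adjusted p = 0.109).

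Proteasome genes rose in the thiolation strains (24 up and 2 down of 32, 27 adjusted over the list alone; PRE3 0.74, RPN2 0.53), with adjusted p = 2.84e-13, and adjusted p = 0.0116 with an estimated correlation. Of 41 Gcn4 targets, 27 rose and 5 fell (32 adjusted over the list alone; LEU4 0.73, LYS2 0.83), with adjusted p = 2.04e-10, and adjusted p = 0.108 with an estimated correlation. Hsf1 chaperones rose (16 up and 1 down of 24, 19 adjusted over the list alone; HSP78 0.69, HSP82 0.47), with adjusted p = 4.53e-04, and adjusted p = 0.490 with an estimated correlation. Ribosomal protein genes fell (4 up and 69 down of 137, 74 adjusted over the list alone; RPL22B −0.69), with adjusted p = 2.13e-09, and adjusted p = 0.490 with an estimated correlation. Pho4 targets (1 up and 11 down of 16, 12 adjusted over the list alone) had adjusted p = 2.40e-04, and adjusted p = 0.490 with an estimated correlation. In all, 1212 genes rose and 868 fell. With the set as a term 1727 were called, 1356 of them among the 2080 and in the same direction, and the split was 925 higher and 1215 lower with median centring and 975 and 1095 without ribosomal protein genes.

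In RNA of the thiolation strains, ARO10 (2.13, SE 0.157), ARO9 (1.38) and ARG4 (1.25) rose, and TIR1 (−1.82), ANB1 (−1.20) and TYE7 (−1.07) fell. Proteasome genes rose (28 up and 1 down of 32; adjusted p = 6.77e-11, and adjusted p = 0.386 with an estimated correlation). Of the mitochondrially encoded genes, 7 of 8 rose (adjusted p = 0.00179, and adjusted p = 0.585 with an estimated correlation). RNA calls were 1333 higher and 637 lower (949 and 916 with median centring, 935 and 903 with quantile normalization), and 1888 with the set as a term. In translational efficiency, YBR056W-A (1.24), CMK2, a calmodulin-dependent kinase gene (0.65), and ESF1, a ribosome assembly gene (0.54), rose, and RPL22B (−0.72) and CPA1 (−0.61) fell. The adjusted p of YBR056W-A was 0.064 with the set as a term. These were among 7 higher and 9 lower of 4253 genes (12 calls with the set as a term, 1 with 1 value per strain; 4 and 8 without ribosomal protein genes; 688 at an unadjusted p under 0.05). The 16 calls changed when single strains were left out: leaving out urm1D gave 442, tum1D 36, ncs2D 10, uba4D 8 and ncs6D 6. Only urm1D lies in set 1, and the other 4 strains lie in set 2. Leaving out urm1D therefore sets strains of 1 set against wild-type libraries of all sets, so strain and set cannot be told apart there.

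Elongator and thiolation strains were set against each other because both act on the same uridine. ARO1 of aromatic amino acid synthesis (difference 0.48), the drug exporter gene QDR2 (0.70) and LEU4 (0.32) lay higher in Elongator strains. The agglutinin anchor gene AGA1 (−1.09), the acid phosphatase gene PHO3 (−0.62) and PRE4 of the proteasome (−0.36) lay lower there than in thiolation strains. The difference passed the limma threshold in 733 genes that were higher in Elongator strains and 342 that were higher in thiolation strains. The Elongator strains lie in all 3 sets (3, 4 and 2 strains) and the thiolation strains in sets 1 and 2 (1 and 4 strains). With the set as a term the counts were 345 and 252, of which 297 and 194 were also called without it in the same direction, and the genes named here kept their direction and their call. Across 4267 genes, which are not independent replicates, the log2 changes of both groups had a Pearson r of 0.819. Unchanged groups simulated against the same wild-type libraries gave a mean r of 0.478 over 100 draws. The covariance was 0.0610 against 0.00258 in the simulation, and 0.0600 (r = 0.796) when each group had its own part of the wild-type libraries. Both groups called 983 genes higher and 528 lower. When each group had its own 7 wild-type libraries, they called 792 higher (306 for independent lists) and 386 lower (97 for independent lists). The r, the covariance and the overlaps are given without the set as a term. A difference between sets that both groups share was not taken out of them, so its part in these values is not known.

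Trm9 with its activator Trm112 adds the last methyl group of that side chain. In trm9D and trm112D (4 libraries), ARO10 (2.53, SE 0.274), ARO9 (1.83), MSN4 (1.61) and MFA1 (1.44, SE 0.205) rose, and PHO5 (−3.00, SE 0.242), TIR1 (−2.79), DDR48 (−2.19), the zinc transporter gene ZRT1 (−1.79) and HIS4 of histidine synthesis (−1.78) fell. Some of these means rest on trm112D: DDR48 was −4.14 there and −0.25 in trm9D, HIS4 −3.14 and −0.42, MFA1 2.56 and 0.33. The mean of MFA1 was 0.91 with the set as a term. YMR173W-A (−2.27) overlaps DDR48, and RPS9A (−2.16) has a near-identical copy, so both values are uncertain. All 16 measured glycolytic genes fell (16 adjusted over the list alone; PGK1 −0.80, ADH1 −0.87, TDH2 −1.47), with adjusted p = 2.51e-22, and adjusted p = 0.00592 with an estimated correlation. The list's median was −1.02 in trm112D and 0.02 in trm9D (adjusted p = 0.897 in trm9D). Proteasome genes rose (29 up and 0 down of 32 by limma, 29 adjusted over the list alone; adjusted p = 2.32e-04, and adjusted p = 0.386 with an estimated correlation). Of the Gcn4 targets 9 rose and 13 fell (22 adjusted over the list alone), with HIS4 and PCL5 (−1.43) lower and LEU4 (0.52) higher; the list stood lower with adjusted p = 2.86e-06, and adjusted p = 0.370 with an estimated correlation. Ribosome biogenesis genes rose (51 up and 1 down of 62, 52 adjusted over the list alone; adjusted p = 0.00169, and adjusted p = 0.787 with an estimated correlation). Sulfur amino acid genes (1 up and 10 down of 17), Pho4 targets (1 and 7 of 16) and aminoacyl-tRNA synthetases (1 and 8 of 19) stood lower at adjusted p of 6.26e-08, 5.07e-09 and 1.41e-06, with adjusted p = 0.105, 0.164 and 0.122 with an estimated correlation. In all, 2168 genes rose and 441 fell (2530 calls with the set as a term). Leaving out trm112D gave 567 calls, against 3033 without trm9D. The results of the lists other than the glycolytic genes are therefore not shown to be shared by both strains. The median change of all genes was 0.20 as deposited and −0.02 with median centring, where the split was 794 higher and 1127 lower (996 and 905 with quantile normalization).

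Sit4 and its Sap partners regulate Elongator by dephosphorylation. In sit4D, sap185D and sap190D (6 libraries), 35 of 35 oxidative phosphorylation genes rose (35 adjusted over the list alone; ATP1 1.01, QCR2 1.06), with adjusted p = 1.83e-36, and adjusted p = 0.000127 with an estimated correlation. Ribosomal protein genes fell (1 up and 104 down of 137, 108 adjusted over the list alone; RPL9A −0.74, RPS2 −0.43), with adjusted p = 1.30e-35, and adjusted p = 0.0316 with an estimated correlation. Msn2/4 stress genes rose (14 up and 0 down of 16 by limma, 14 adjusted over the list alone; the trehalose genes TSL1 1.34 and TPS1 0.66), with adjusted p = 5.12e-06, and adjusted p = 0.490 with an estimated correlation. The median of the oxidative phosphorylation genes was 2.16 in sit4D, 0.14 in sap190D and 0.09 in sap185D. The 3 strains together had 1162 genes higher and 736 lower (1175 calls with the set as a term). Singly, 1151 genes were higher and 1016 lower in sit4D, 380 and 207 in sap190D, and 18 and 8 in sap185D. The ribosomal protein and Msn2/4 results are therefore not shown to be shared by all 3 strains.

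Trm7 methylates riboses in the anticodon loop together with Trm732 or Rtt10. Over trm7D, trm732D and rtt10D (6 libraries), SNZ1 (3.26, SE 0.244) and its neighbour SNO1 (2.91) rose most, but SNZ1 ranged from 0.44 to 8.88 in the single strains. The SE does not cover that spread between strains. ARG1 (2.86, SE 0.170) and ARG3 (2.21) of arginine synthesis rose, and so did TMT1, a methyltransferase gene (1.98). The phosphate-regulated gene PHM6 (−1.69), the mating genes AGA1 (−1.48), FUS1 (−1.31) and MFA1 (−1.25), and the cell wall genes CWP1 (−1.37) and CWP2 (−1.22) fell, with MFA1 at −0.55 and CWP2 at −0.72 with the set as a term. In the single strains ARG1 ranged from 0.54 to 6.57, TMT1 from 0.27 to 5.18, PHM6 from −4.67 to −0.08 and CWP1 from −3.09 to −0.05. Of 41 Gcn4 targets, 41 rose and 0 fell by limma (41 adjusted over the list alone; ASN1 0.91, LEU4 0.96), with adjusted p = 4.42e-67, and adjusted p = 3.5e-08 with an estimated correlation. In the single strains 41 of 41 rose in trm7D (median 2.32), 8 in rtt10D (median 0.19) and 0 in trm732D (median 0.08, 0 genes lower). Ribosomal protein genes (4 up and 79 down of 137, 87 adjusted over the list alone), ribosome biogenesis genes (0 and 38 of 62, 42 adjusted over the list alone), Pho4 targets (0 and 11 of 16, 12 adjusted over the list alone) and a-specific genes (0 and 5 of 7, 6 adjusted over the list alone) fell at adjusted p of 4.13e-15, 1.03e-07, 5.29e-07 and 7.05e-04. With an estimated correlation these adjusted p were 0.346, 0.490, 0.305 and 0.386. Over all genes 725 were lower in trm7D, 197 in rtt10D and 2 in trm732D, so these lists are not shown to fall in all 3 strains. In all, 960 genes rose and 696 fell (721 and 924 with median centring, 737 and 898 with quantile normalization). With the set as a term 827 were called, 651 of them among the 1656 and in the same direction and 1 in the other, and leaving out trm7D gave 642; YOR235W (−1.64), ADH2 (−1.55) and YHR180W-A (1.75) became −0.89 (adjusted p = 0.063), −0.45 and −0.31 with the set as a term.

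Over bud32D, cgi121D and gon7D, the KEOPS strains (6 libraries), SNZ1 rose by 6.10 (SE 0.244), SNO1 by 5.08, HSP12 by 4.10 (SE 0.368), ARG1 by 4.10 (SE 0.170) and GCN4 by 2.93 (SE 0.168; 2.33 with the set as a term). HSP12 ranged from 0.75 to 6.66 in the single strains. TIR1 (−4.00, SE 0.132), the phosphate genes PHO12 (−3.92), PHO5 (−3.80), PHM6 (−3.78) and PHO89 (−3.73), ZRT1 (−3.51) and the iron-uptake cell wall gene FIT1 (−3.42) fell. Of 137 ribosomal protein genes, 0 rose and 131 fell by limma (132 adjusted over the list alone; RPS3 −0.82, RPL3 −0.73), with adjusted p = 3.07e-46, and adjusted p = 0.00818 with an estimated correlation. Of 41 Gcn4 targets, 40 rose and 0 fell (41 adjusted over the list alone; LEU4 1.53, ASN1 1.48), with adjusted p = 7.14e-22, and adjusted p = 0.0046 with an estimated correlation. Of 16 Pho4 targets, 0 rose and 15 fell (15 adjusted over the list alone; VTC3 −2.26, VTC4 −1.37), with adjusted p = 3.56e-13, and adjusted p = 0.0391 with an estimated correlation. All 16 Msn2/4 stress genes rose (16 adjusted over the list alone; HOR7 2.14, TSL1 2.30), with adjusted p = 3.28e-05, and adjusted p = 0.528 with an estimated correlation. Of the a-specific mating genes, 7 of 7 fell (7 adjusted over the list alone; BAR1 −2.22, STE2 −1.63), with adjusted p = 2.80e-05, and adjusted p = 0.230 with an estimated correlation. Oxidative phosphorylation genes (32 up and 1 down of 35, 33 adjusted over the list alone; adjusted p = 5.07e-09, and adjusted p = 0.214 with an estimated correlation) rose, and ribosome biogenesis genes (1 up and 47 down of 62, 48 adjusted over the list alone; adjusted p = 3.56e-13, and adjusted p = 0.292 with an estimated correlation) fell. In all, 2138 genes rose and 1031 fell, and with the set as a term 2789 were called, 2601 of them among the 3169 and in the same direction and 1 in the other. The median change of all genes was 0.17 as deposited and −0.03 with median centring, where the split was 1348 higher and 1653 lower (1407 and 1586 with quantile normalization, 1615 and 1414 without ribosomal protein genes).

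**Figure D2:**
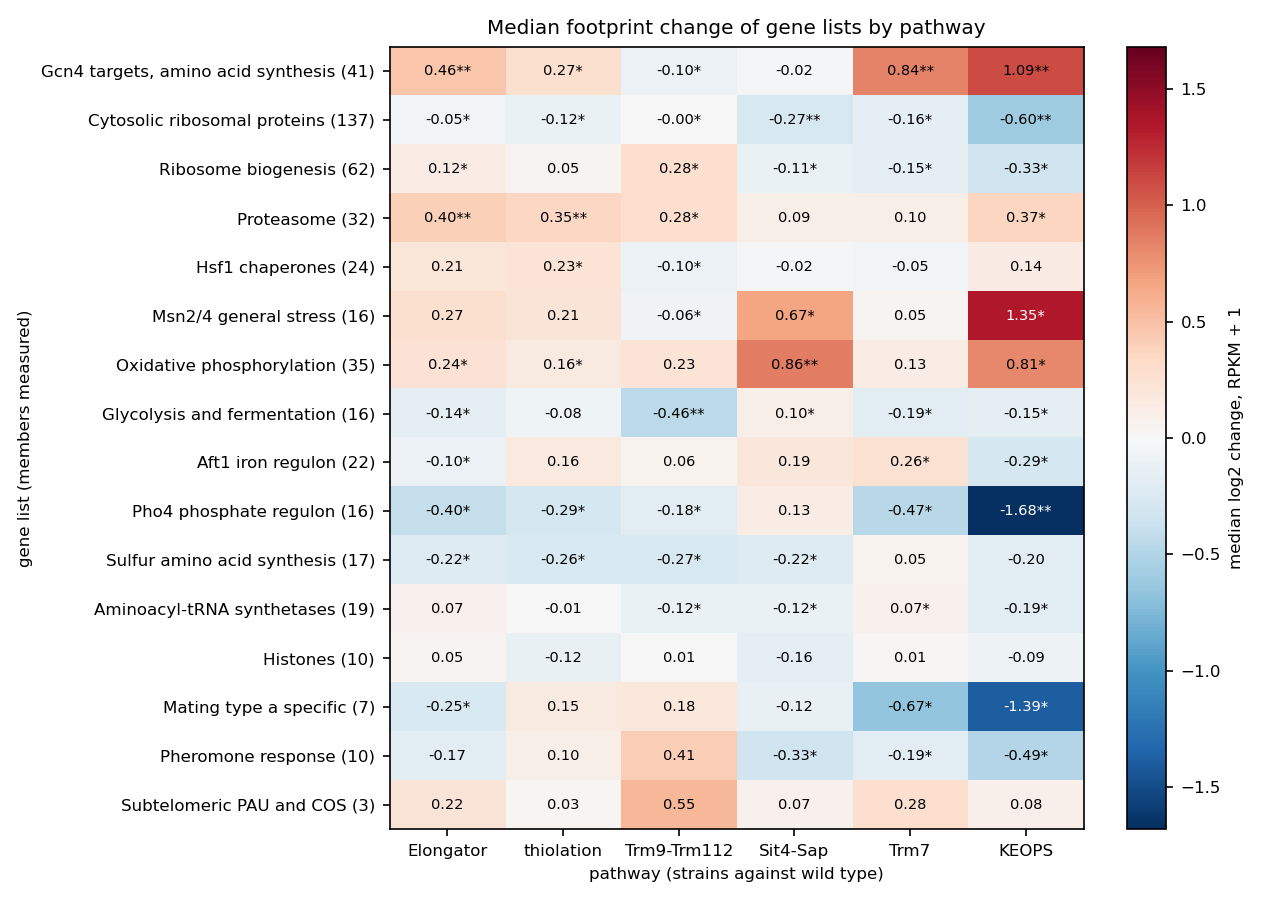
Median log2 footprint change of the gene lists fixed beforehand (y axis) in each group of strains (x axis; colour, log2 change against wild type); * marks adjusted p under 0.05 by camera with a preset correlation and ** also with an estimated correlation. Gcn4 targets reach a median of 1.09 and ribosomal protein genes −0.60 in the KEOPS strains.

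GCN4 (YEL009C; chromosome V, 138918 to 139763, minus strand, sacCer3) is translated under control of upstream open reading frames and serves as a classical readout of tRNA and initiation status. Its footprints in wild type were 39.2 ± 28.1 RPKM (SD, n = 14), or 29.4 ± 1.99 in set 1 (n = 6), 29.6 ± 4.11 in set 2 (n = 4) and 63.5 ± 47.9 in set 3 (n = 4), where 1 library reached 134. They were higher in 23 of 56 strains (limma, adjusted over strains). The rise was largest in trm7D (log2 change 4.91, SE 0.261; 1006 and 1156 RPKM), pus3D, which lacks a pseudouridine synthase (4.34; 688 and 764 RPKM), and cgi121D (4.10). It was 2.89 in gon7D, 2.69 in rit1D, which lacks the enzyme that marks the initiator tRNA, 2.00 in pus7D, 1.89 in trm1D and 1.10 in mod5D. Of the Elongator strains with 2 libraries all were called, from 0.69 in kti12D (adjusted p = 0.0225) to 2.16 in elp6D. Of the thiolation strains, ncs2D (1.62), ncs6D (1.57), uba4D (1.5) and urm1D (1.33) were called, and tum1D had 0.57 (adjusted p = 0.0713). The call of tyw3D (0.80) rests mainly on 1 library, with 104 and 35.9 RPKM. In trm112D GCN4 was lower (−0.76, adjusted p = 0.0109; −0.52 and adjusted p = 0.110 with the set as a term). The RNA of GCN4 in wild type was 656 ± 36.6 RPKM (SD, n = 10), and its change in the 23 strains, with 1 RNA library each, lay between 0.07 and 0.84. All 23 calls were kept with the set as a term, where 24 strains were higher. There were 19 strains higher against the mean of all deletion strains, where kti12D, rtt10D and tyw3D reversed, 19 without replicate 1, 18 without replicate 2 and 22 without the doubted libraries.

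**Figure D3:**
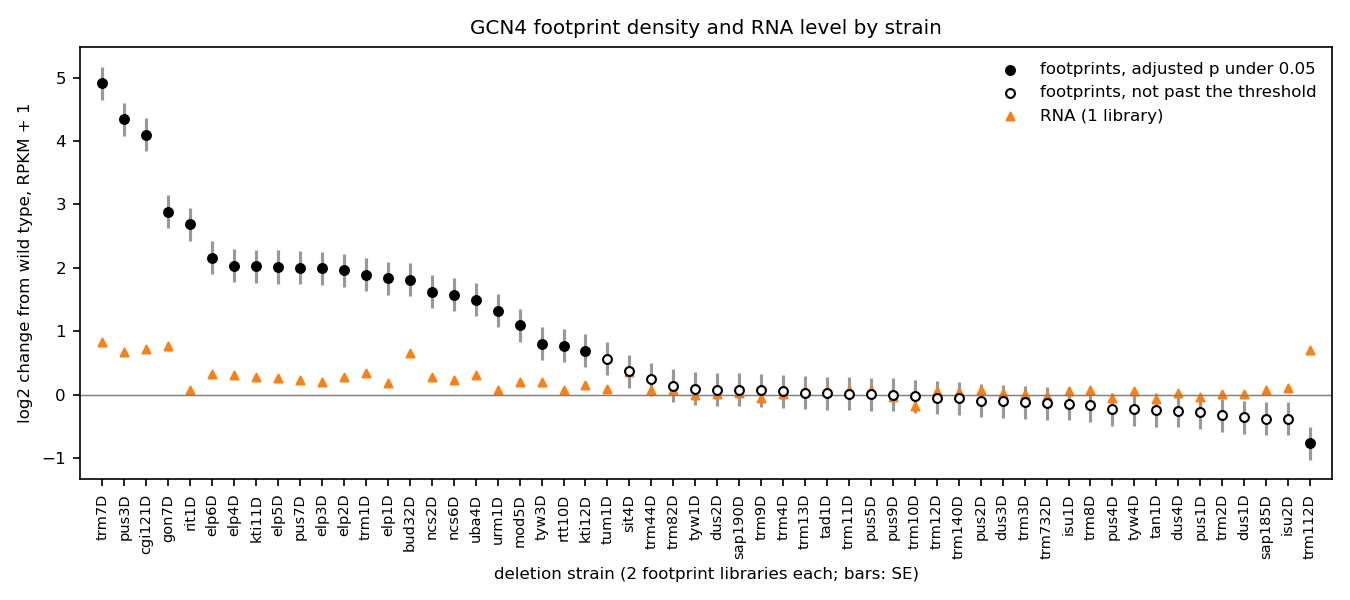
Log2 change of GCN4 footprints and of GCN4 RNA against wild type (y axis) in each strain with 2 footprint libraries (x axis); error bars are the standard error of the footprint change, and RNA has 1 library per strain. The footprint change is 4.91 in trm7D and 4.34 in pus3D, while the RNA change of the 23 called strains stays at or below 0.84.

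The Gcn4 targets as a list stood higher in 25 strains and lower in 11 (camera, adjusted over all lists and strains; 14 higher with an estimated correlation). In rit1D 40 of 41 rose (median 0.97; adjusted p = 2.31e-148, and adjusted p = 1.16e-14 with an estimated correlation). In pus3D 40 rose and 1 fell (median 1.5), in cgi121D 41 rose (median 1.93), in pus7D 36 rose (median 0.54) and in trm1D 31 rose (median 0.60). Over all 7 pseudouridine synthase strains 36 rose and 0 fell by limma (37 adjusted over the list alone; ARO4 0.38, HOM3 0.40), with adjusted p = 8.92e-50, and adjusted p = 1.6e-06 with an estimated correlation. This mean rests on pus3D and pus7D: in the other 5 strains the list's median lay between −0.10 and 0.07 and the change of GCN4 footprints between −0.28 and 0.00. Proteasome genes stood higher in 21 strains and lower in 0 (5 with an estimated correlation), and oxidative phosphorylation genes higher in 17 and lower in 0 (1 with an estimated correlation). Ribosomal protein genes stood higher in 2 strains and lower in 34 (3 with an estimated correlation), Pho4 targets in 1 and 22 (2), glycolytic genes in 6 and 15 (1), aminoacyl-tRNA synthetases in 8 and 20 (1) and a-specific genes in 2 and 10 (1). Ribosome biogenesis genes stood higher in 5 and lower in 23 strains, Hsf1 chaperones in 12 and 2, Msn2/4 genes in 8 and 6, the Aft1 regulon in 11 and 9, sulfur amino acid genes in 4 and 9, pheromone response genes in 1 and 10, histones in 2 and 3 and PAU and COS genes in 0 and 1, and in 0 strains each with an estimated correlation. With the set as a term, the counts higher and lower were 23 and 14 for Gcn4 targets, 22 and 0 (proteasome), 19 and 1 (oxidative phosphorylation), 2 and 48 (ribosomal proteins), 2 and 26 (Pho4), 2 and 30 (glycolysis), 3 and 17 (synthetases) and 2 and 18 (a-specific). They were 7 and 24 for ribosome biogenesis, 12 and 3 (Hsf1), 12 and 6 (Msn2/4), 11 and 12 (Aft1), 4 and 17 (sulfur), 4 and 11 (pheromone response), 3 and 2 (histones) and 1 and 0 (PAU and COS).

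Groups of strains that lack other modifications had calls that the set term mostly removed. Calls fell from 1120 to 99 in the 4 wybutosine strains, from 976 to 3 in the 2 strains lacking the methyltransferase of guanosine in the variable loop (trm8D and trm82D), from 541 to 5 in the 4 dihydrouridine strains, from 457 to 113 in the pseudouridine strains and from 343 to 4 in the Isu strains, which lack iron-sulfur scaffold proteins. In RNA, where a strain has 1 library and no test was made, the number of genes at least 2-fold from the wild-type mean and outside the range of all wild-type libraries had a median of 6 over strains (1 to 771). The same count for each wild-type library against the others had a median of 0 (0 to 3). It was 771 in bud32D, 570 in gon7D, 215 in sit4D, 146 in trm7D, 139 in trm112D and 107 in pus3D.

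Codon occupancy, the share of footprints with a given codon at a ribosomal site relative to wild type, asked which codons were decoded differently. It was measured in cycloheximide-treated libraries alone. At the A site, where the next tRNA is selected, the Elongator strains had more ribosomes at AAA, CAA and GAA, the lysine, glutamine and glutamate codons read by tRNAs with the fully modified uridine. The mean log2 change over these codons was 0.240 ± 0.0331 (SD, n = 9 strains) against 0.0153 ± 0.029 (n = 36) in strains outside the wobble uridine pathways, with 9 of 9 above the others' mean (exact permutation p = 1.13e-09, two-sided, the smallest possible). In the thiolation strains the mean was 0.267 ± 0.0598 (n = 5; exact permutation p = 1.33e-06, the smallest possible). AAA, CAA and GAA changed by 0.22, 0.37 and 0.13 in Elongator strains and by 0.33, 0.37 and 0.10 in thiolation strains. Within set 1 the Elongator difference was 0.273 (exact permutation p = 0.00833), within set 2 0.189 (p = 4.21e-05) and within set 3 0.228 (exact p = 0.1, the smallest 2 strains against 3 can give). In set 3 the comparison strains are the KEOPS strains, whose AAA occupancy was itself lower, so that difference is not measured against unchanged strains. Within set 2 the thiolation difference was 0.236 (exact permutation p = 4.21e-05). Elongator and thiolation strains differed at AAA by −0.11 (exact permutation p = 0.02, adjusted p = 0.0799), which did not pass.

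**Figure D4:**
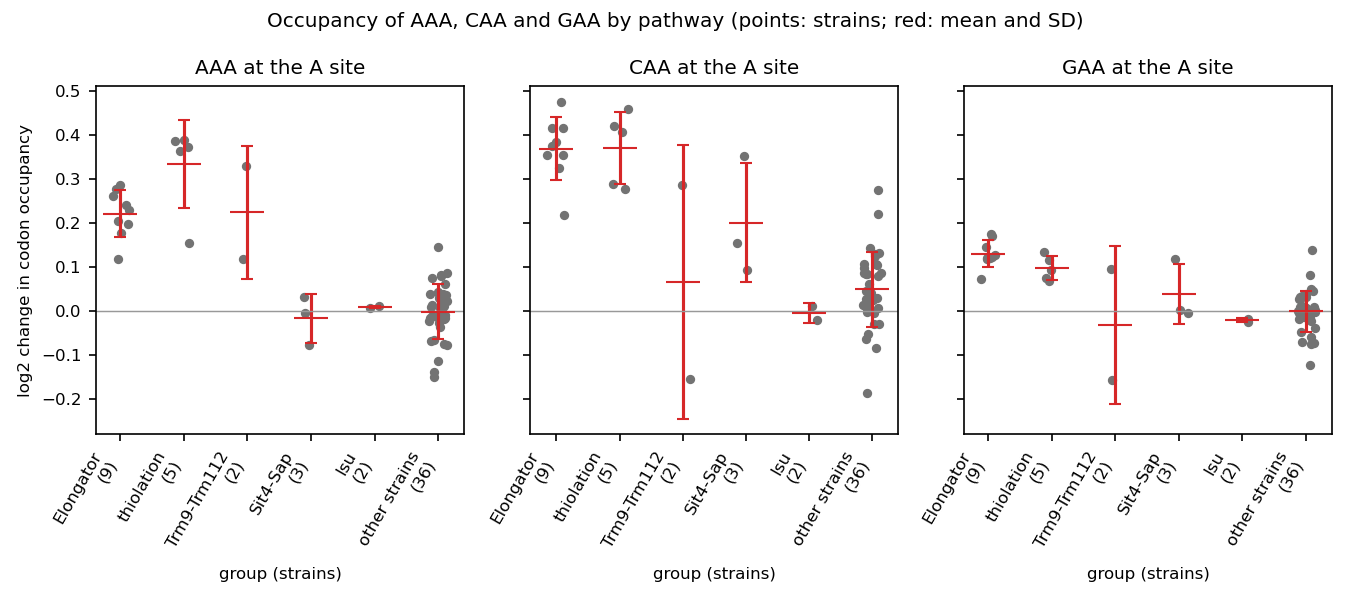
Log2 change of A-site occupancy against wild type (y axis) at AAA, CAA and GAA in single strains (points) of the wobble uridine pathways and of the 36 other strains (x axis); red marks are group means and SD. The means of Elongator strains are 0.22, 0.37 and 0.13, and those of thiolation strains 0.33, 0.37 and 0.10.

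The KEOPS strains had fewer ribosomes at 11 of the 16 codons that begin with A, by exact permutation tests over 3 strains against 33. AAA differed by −0.15 (adjusted p = 0.000638), AUA by −0.12 (adjusted p = 0.00115) and ACC by −0.11 (adjusted p = 0.00209), and AGG was higher by 0.07 (adjusted p = 0.0154). All 3 belong to set 3, which holds 0 strains of the comparison. Against the 4 wild-type libraries of set 3, by limma with the set as a term, 11 of the 16 were lower and 0 higher, with AAA at −0.135 (adjusted p = 7.05e-04) and AUA at −0.137 (adjusted p = 0.00643), while ACG (adjusted p = 0.167) and AGG (adjusted p = 0.0872) did not pass. Against the set's other strains, elp5D, kti13D and trm9D, which was not tested, 11 of the 16 were lower by the mean. In the wybutosine strains, which lack steps of the base that flanks the anticodon of phenylalanine tRNA, the phenylalanine codons UUU and UUC were higher by 0.19 and 0.16 (n = 4 against 32, exact permutation, adjusted p = 0.00512 and 0.00626; within set 2, which holds all 4, 0.20 and 0.16). UUU was 0.26 in trm12D, 0.32 in tyw1D, 0.36 in tyw3D and −0.01 in tyw4D, which lacks the last methyl transfer. AAA was higher in trm9D and trm112D (difference 0.23, exact permutation, n = 2 against 36, adjusted p = 0.00729), and CAA in the Sit4 and Sap strains (0.15, n = 3, exact permutation, adjusted p = 0.0222). CAA was 0.35 in sit4D, 0.15 in sap190D and 0.09 in sap185D, against 0.049 ± 0.085 (SD) in the 36 comparison strains. AAA was 0.12 in trm9D and 0.33 in trm112D. Within its set the AAA difference was 0.31 for trm112D (set 2) and 0.25 for trm9D (set 3), the latter against the KEOPS strains, whose AAA was lower. The other target codons of these groups did not pass by exact permutation: CAA (0.02), GAA (−0.03), AGA (0.01) and GGA (−0.13, adjusted p = 0.0653) in trm9D and trm112D, and AAA (−0.02) and GAA (0.04) in the Sit4 and Sap strains. At CAA and GAA, trm9D and trm112D went opposite ways, so their means hide the single strains. CAA was 0.29 in trm9D and −0.15 in trm112D, and GAA was 0.095 and −0.16. The Trm7 group did not differ at UUU, UUC and UGG (difference −0.01, n = 3 against 33, exact permutation p = 0.818). The 33 strains include trm12D, tyw1D and tyw3D, with UUU higher, and the KEOPS strains. UGG was 0.57 in bud32D, 0.31 in cgi121D and 0.72 in gon7D, so that difference is not measured against unchanged strains. Within set 1 alone the Trm7 group was 0.0745 higher (exact permutation p = 0.0286). UUU was 0.23 in trm7D, 0.18 in rtt10D and 0.01 in trm732D. None of the codons tested passed in the Isu strains, and 24 of the 41 tests of this family passed at an adjusted p under 0.05.

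In tan1D, which lacks the acetylation of leucine and serine tRNAs, all 12 leucine and serine codons were lower at the A site and higher at the P site, where the growing chain is held. UUA changed by −1.29 (SE 0.0645) and UUG by −1.27 (SE 0.0389) at the A site, the largest changes of all 3477 strain-codon pairs. CUU rose by 0.63 at the P site. The mean over the 10 codons set down for this strain was −0.59 at the A site, where the other 56 strains lay between −0.30 and 0.14, and 0.31 at the P site, where they lay between −0.07 and 0.09. The mean over 8 codons of mod5D, which lacks the isopentenyl group next to the anticodon, was −0.30 at the A site (8 of 8 lower; other strains −0.16 to 0.10). In trm140D, which lacks a methylated cytidine of threonine and serine tRNAs, the 4 threonine codons were 0.23 higher at the P site (other strains −0.06 to 0.12). For 1 strain against 56 the smallest possible exact permutation p is 0.0175, which these reached, with an adjusted p of 0.0526 over 12 tests. The inosine strain tad1D (0.01 at the A site), trm44D (−0.07) and rit1D at AUG (0.01) lay inside the range of the others. Other large A-site changes were UUA in pus4D (−0.91) and trm1D (−0.72), CGG in gon7D (0.82) and bud32D (0.73), UGG in gon7D (0.72) and CAC in trm112D (−0.64). Over all strains 428 pairs were higher and 351 lower at the A site (limma, adjusted p under 0.05), of 3477 from 61 codons and 57 strains. Of these calls 15 belong to kti13D, which has 1 library and was tested with the variance of the other strains. With the set as a term 540 pairs were called.

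**Figure D5:**
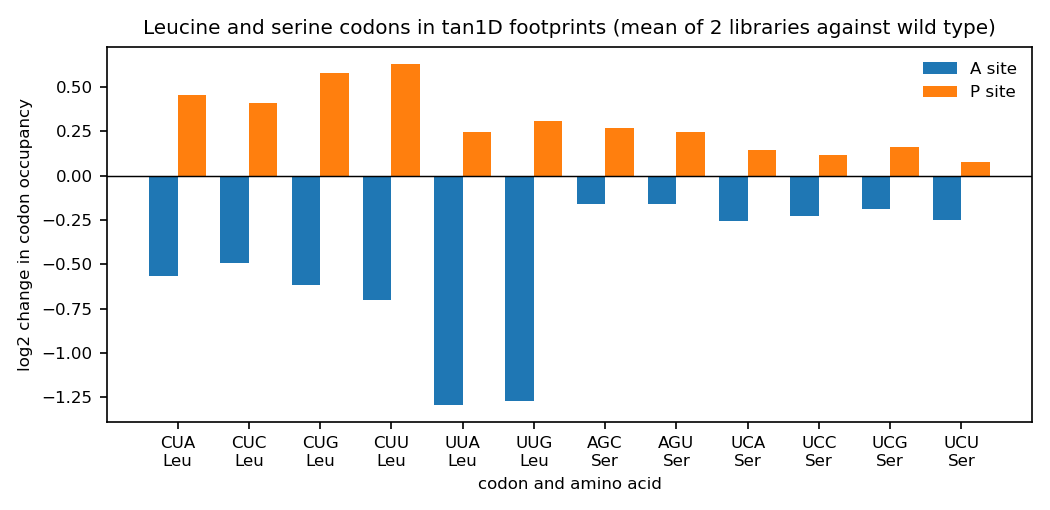
Log2 change of codon occupancy in tan1D against wild type at the A site and the P site (y axis) for the leucine and serine codons (x axis). UUA (−1.29) and UUG (−1.27) are lowest at the A site, and all 12 codons are above 0 at the P site.

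RiboMeth-seq scored each rRNA position by its lack of fragment ends relative to its neighbours, which is near 1 where the ribose is methylated. In wild type 126 positions were protected, 78 in 25S rRNA (chromosome XII, 451786 to 455181, minus strand), 40 in 18S rRNA (455933 to 457732), 8 in 5.8S rRNA (455414 to 455571) and 0 in 5S rRNA. These positions were picked by score alone and not set against known methylated sites, so a protected position need not be methylated. The strains trm3D, trm7D, trm13D, trm44D, trm732D and rtt10D (n = 2 libraries each) kept mean scores between 0.959 and 0.962. In each of them 0 of the 126 positions fell under 0.5 in both libraries, and single positions changed by −0.0336 to 0.0343 at most. These changes were not tested. The sites set down beforehand for these strains lie in tRNA, which the counts do not cover. Kept rRNA scores therefore do not test the loss of these enzymes. In 6 further libraries of each strain, paired by their labels, the mean score exceeded wild type by 0.00194 in trm7D (5 of 6 higher) and by 0.00179 in trm3D (6 of 6 higher). With the 3′ ends of the rRNAs kept these differences were −0.0184 and 0.00827. No p is given, since the 6 differ in end treatment and a label number and are not shown to come from separate RNA samples.

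Footprints made without cycloheximide asked whether the changes depended on the drug, with 1 library per strain and no test. ARO10 was 3.76 higher without the drug and 3.44 with it in elp3D, and 4.99 and 4.53 in trm7D, where ARG1 was 6.57 in both. GCN4 without the drug was 5.57 higher in trm7D, 2.44 in elp3D, 1.56 in mod5D, 1.12 in tyw4D (−0.23 with the drug) and 0.27 in tan1D. ARG1 in tyw4D was 1.72 without and −0.30 with the drug. Across 4122 genes, which are not independent replicates, the changes with and without the drug had a Pearson r of 0.909 in trm7D, 0.762 in elp3D, 0.361 in mod5D, −0.0395 in tan1D and −0.0606 in tyw4D (Spearman rho 0.773, 0.657, 0.273, −0.0505 and −0.0536). The highest r of a strain's drug-free change with the drug-treated change of another of these strains was 0.296 for trm7D, 0.335 for elp3D, 0.245 for mod5D, 0.0245 for tan1D and 0.281 for tyw4D, which for tan1D and tyw4D exceeds their own r. The drug-treated changes were taken against all 14 wild-type libraries, without the set. With the set as a term tan1D and tyw4D had 2 and 4 calls, so their low r says little about the drug. All drug-free changes share 1 wild-type library. The footprints left at the deleted gene in these libraries were 1.17% to 2.17% of the drug-free wild type.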

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

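The splits of the libraries and the tests of the 3 patterns below were chosen after the results were seen.

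The difference between Elongator and thiolation strains passed the threshold in 733 genes higher in Elongator strains, such as QDR2 and ARO1, and 342 genes higher in thiolation strains, such as AGA1 and PHO3, and with the processing set as a term in 345 and 252. It was looked at because a difference between groups was tested directly. Codon occupancy at the P and E sites, which the comparisons set down beforehand hardly used, held 831 and 319 called strain-codon pairs of 3477, with 8 and 1 of them in kti13D, which has 1 library. At the P site the largest were UUA in trm1D (−0.67), CGG in trm112D (−0.63) and CUU in tan1D (0.63), and at the E site CGA in trm112D (0.25) and kti11D (−0.24). Library 5 of the further trm3D libraries stood apart in depth, with 17.3 M 5′ ends against 20.4 M in the nearest of its group. This was 1 of 8 groups looked at, and chance makes about 1 in 20 groups stand out.

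Other splits of the libraries were counted for each group result, 100 splits each with the real one included, and in each case only the real split (1 of 100) gave a count as large. Footprint calls were 2335 against at most 1247 in another split for Elongator, 2080 against 1391 for thiolation and 1656 against 1221 for Trm7 strains. Another split came closer for trm9D and trm112D (2609 against 2463) and for KEOPS strains (3169 against 2800). RNA calls were 2373 against 0 (Elongator) and 1970 against 143 (thiolation), and calls of translational efficiency 82 against 5 and 16 against 0. These splits move single libraries, so the libraries of a strain need not stay together and variation between strains is not covered. They therefore cannot exclude that a chance choice of strains gives counts as large. With 1 value per strain, set against strains of other pathways, footprint calls were 1289 (Elongator), 123 (thiolation), 525 (trm9D and trm112D), 634 (Trm7) and 2210 (KEOPS), and with 1 value per strain calls of translational efficiency were 290 (Elongator) and 1 (thiolation).

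Some strains with modest changes lost most calls with the processing set as a term, while others, such as pus7D (284 to 169) and rit1D (256 to 136), did not. Of 41 strains in a set with at least 20 calls, 13 fell under 20, among them trm8D (668 to 2), pus4D (631 to 3) and tan1D (252 to 2). The subunit partners trm8D (668) and trm82D (10) differed without the term and had 2 calls each with it. A difference between processing sets is a candidate explanation for the calls of these 13 strains, and a real change of small size stays open. In each of the 5 pathway groups at least 827 genes were called with the term, against 214 (5% of the genes tested), so a difference between sets was not the whole source there.

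GCN4 footprints rose in 23 strains without a matching rise of its RNA. If RNA abundance were the source, the RNA change would reach at least 0.5 of the footprint change, and it did so in 0 of the 23. With the processing set as a term 23 kept their call. The number of strains was 18 to 24 under the other settings, and 3 strains (kti12D, rtt10D and tyw3D) reversed against the mean of all deletion strains. Changed translation of GCN4 may be the source, as a hypothesis, since the upstream reading frames were not measured here.

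In tan1D all leucine and serine codons were lower at the A site and higher at the P site. Reads assigned to the wrong codon could move other codons as far. The largest change of any other codon was 0.31, below the smallest leucine change (0.494 in size), but 7 of the 49 others were at least as far as the smallest serine change (0.162 in size). For the serine codons that explanation stays open. A wrong assignment limited to leucine and serine footprints would not move other codons, so this comparison cannot test it for either amino acid. A difference of the set could lower the codons in its other 38 strains, but their median was 0.039 (SD 0.101) over the leucine codons, against −0.82 in tan1D, and 0.0085 (SD 0.0553) over the serine codons, against −0.21. The lowest of them, trm1D, had −0.31 and −0.21. What the lost acetyl group does to decoding was not tested.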

How the results depend on the processing

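The processing set, the doubted libraries and the codon tests within a set were tests chosen after seeing the data, and the other alternatives were planned. Of 260 named values under 2297 settings, 2242 kept their direction and side of the threshold, 51 no longer passed and 4 reversed. Of 21 summary results under 293 settings, 239 were kept (counts within 1.5 times) and 54 changed. The cause was not tested, except that fewer genes or samples enter under a stricter filter, with 1 value per strain, or when libraries are left out. How far depth limits the calls was not tested.

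With a mean of at least 50 RPKM, calls were 24931 in single strains, 1290 in Elongator, 1239 in thiolation, 1253 in trm9D and trm112D (mcm5_methyl), 970 in Trm7_complex and 1588 in KEOPS strains. RNA calls were then 1204 (Elongator) and 1071 (thiolation), TE calls 44 and 10, and the median of RNA genes outside the wild-type range was 3. With an additional 1.5-fold threshold, calls were 170 (Elongator), 123 (thiolation), 434 (mcm5_methyl), 159 (Trm7_complex) and 1031 (KEOPS). With 1 value per strain they were 1289, 123, 525 (mcm5_methyl) and 634 (Trm7_complex), and in TE 290 and 1. Without replicate 1 or 2, the ranges were 15215 to 15685 in single strains, 25 to 26 strains with at least 20 calls, 1212 to 1270 (thiolation), 1386 to 1702 (mcm5_methyl), 434 to 583 (Trm7_complex), 52 to 89 (TE, Elongator) and 15 to 59 (TE, thiolation). Leave-one-out of strains gave 1798 to 2233 (thiolation), 567 to 3033 (mcm5_methyl), 642 to 1798 (Trm7_complex), 51 to 108 (TE, Elongator) and 6 to 442 (TE, thiolation). With the processing set as a term, Trm7_complex had 827 calls, TE of Elongator 382, and YHR180W-A in Trm7_complex reversed to −0.31. With the mean of all deletion strains as reference, Trm7_complex had 2535 calls, and GCN4 reversed to −0.12 in kti12D, −0.0473 in rtt10D and −0.0148 in tyw3D. With no filter TE calls were 195 (Elongator) and 33 (thiolation), with edgeR 129 and 77, and without doubted libraries 10 for thiolation. The Gcn4 list stood higher in 14 strains with an estimated correlation. Within set 3 the Elongator codons differed from those of the KEOPS strains, the comparison strains there, by 0.228 (exact permutation p = 0.1), and within set 1 the Trm7 codons by 0.0745 (exact permutation p = 0.0286). With the replicate block, calls were 39793 in single strains, 2349 in Elongator, 2091 in thiolation, 2617 in mcm5_methyl, 1666 in Trm7_complex and 3182 in KEOPS strains, with 79 and 15 in TE and 799 codon pairs. Over all pairs of strains the numbers do not pair the libraries (median r of 0.014 between strains' replicate differences). In set 1, replicate 2 was the deeper library of every strain (elp3D, 4.73 and 10.8 M reads), so a pairing within that set stays open.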

Other observations

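The codon pairs and strains of this part were chosen, and their tests made, after seeing the data. The strains trm8D and trm82D lack the partner subunits of the enzyme that methylates a guanosine in the variable loop of tRNA, and their codon profiles at the P site went together. Ribosomes with the valine codon GUG at the P site were more frequent in both, by 0.59 (SE 0.036) in trm8D and 0.59 in trm82D, while the other 55 strains lay between −0.19 and 0.17 (exact permutation p = 0.000627, the smallest possible, adjusted p = 0.0382 over 61 codons at 3 sites). The cysteine codons UGC (−0.53 and −0.48; other strains −0.21 to 0.15) and UGU (−0.48 and −0.38; other strains −0.20 to 0.20) were less frequent, with the same p. These 3 codons alone passed of 183 tests. GUC (0.28 and 0.31) and GUU (0.17 and 0.26) did not pass (exact permutation, adjusted p = 0.367 and 0.382).

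Over 61 codons, which are not independent replicates, the P-site changes of trm8D and trm82D had a Pearson r of 0.910. The next highest r was 0.520 for trm8D (with trm13D) and 0.404 for trm82D (with urm1D). At the A site their r was 0.346, below that of trm8D with gon7D (0.871), and at the E site 0.615, where trm8D and trm13D had 0.601. Both strains had 2 footprint calls each with the processing set as a term.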
